A study of Mus musculus with 5 samples.

How the data were processed

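Total RNA had been isolated from snap-frozen tissue of liver lobe 1, and libraries had been made with the TruSeq RNA kit and sequenced on an Illumina HiSeq instrument, per the labels' protocols. The submitters' processing notes name TopHat, an aligner for spliced reads, and the mouse build mm10. The version of TopHat, the counting tool and the gene annotation are not given in the sources used here, nor is whether counting used the strand. The files deposited by the authors hold estimated counts per Ensembl gene, a table for each library, with 36401 identifiers and their symbols. The deposited estimated counts are not scaled to depth or gene length. Of the values above 0, 33.9 to 37.3% were whole numbers (tolerance 1e-06) and the others fractions, as when a read that maps to several genes is shared among them. Counts of near-identical genes, of overlapping genes and of antisense pairs are therefore uncertain.

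Library totals ranged from 11944157 to 17312851 estimated counts, and 18899 to 19536 genes had a value above 0. A floor of 3 counts corresponds to 0.173 to 0.251 CPM per library, and such floors cover counting error only. Samples were grouped by the genotype in their labels, 2 Mdr2+/+ and 3 Mdr2+/-. No pair of libraries agreed within sampling noise: the chi-square per degree of freedom over genes with at least 20 counts in a pair was 5.31 to 8.85 within a genotype and 18.3 to 26.0 between genotypes.

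Estimated counts were rounded to whole numbers, which changed a library's total by 201 to 309 counts. Genes were kept by filterByExpr in edgeR 4.0.16 (minimum count 10), which left 13959 genes holding 99.9% of the counts, and libraries were scaled by TMM. Heterozygous libraries were compared with wild-type libraries by the quasi-likelihood test of edgeR (glmQLFit and glmQLFTest, two-sided, no covariate), with Benjamini-Hochberg adjustment over all tested genes and a threshold of 0.05. Fold changes are heterozygous minus wild-type on the log2 scale, and the SE is the fold change divided by the square root of the F statistic. The common biological coefficient of variation was 0.0762 and the prior degrees of freedom 6.52. All work was done in R 4.3.3 with limma 3.58.1 and DESeq2 1.42.0, and figures were drawn in Python.

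Gene lists, 33 in number, were written before the data were examined, as were the tests, most alternative settings and the rule for naming genes. Lists with at least 5 tested members (30) were tested by camera in limma on log2 CPM (prior count 2) with a preset inter-gene correlation of 0.01, and adjusted p-values run over these lists. Camera called 14 lists, 7 higher and 7 lower, and 0 with a correlation estimated for each list, where 2 had an unadjusted p under 0.05. The directional test fry called 6; it asks whether a list's genes move, on balance, in a single direction and does not compare them with other genes. The rule named Abcb4, the 12 genes with the largest rise and the 12 with the largest fall among those past the threshold whose groups did not overlap, and up to 4 members of each list by p-value. Genes named outside this rule were chosen after their values were seen, which is said beside them. Some genes that the rule names are not reported here.

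Gene coordinates, transcript lengths and GC content came from GENCODE release M21 on the same mouse build as the processing notes name, matched by Ensembl identifier. Of the identifiers, 31782 (87.3%) matched, and 97.2% of the tested ones did; length and GC content are those of the longest transcript unless stated otherwise. The alternatives were 2 other filters, 2 other scalings, the DESeq2 Wald test, limma with robust variances, limma with sample weights, the replicate number as a block, each library left out, an estimated correlation and fry, and, chosen after seeing the data, offsets for GC content and for transcript length. Simulated counts with the real means and library sizes were used to test the procedure. Of genes changed by 0.5, 1 and 2 on the log2 scale, 48.5% of 66, 85.1% of 67 and 100% of 62 were recovered, and 6.79% of the calls fell on unchanged genes. Each simulated gene varied only as much as is typical at its expression level, so these shares do not cover genes that vary more. A simulated list of 20 genes shifted by 0.5 was called with both kinds of correlation, and 0 of 29 unshifted lists were. Simulated genes were drawn independently, so this cannot show how often the list test errs when members move together. Estimated correlations of the real lists ran from -0.08 (sex-linked and sex-biased genes) to 0.77 (cholesterol synthesis). Dixon's outlier test was not applied to these groups of 2 and 3 libraries.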

Results

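Liver RNA was profiled by sequencing in BALB/C mice on day 10 of life. Lobe 1 of the liver was sampled, and Mdr2+/+ (wild-type) pups gave 2 libraries while Mdr2+/- (heterozygous) pups gave 3. Mdr2 is the older name of Abcb4, which encodes the canalicular floppase that moves phosphatidylcholine from hepatocytes into bile. The series title links low ABCB4 to inflammation in biliary atresia, a fibro-inflammatory disease of the newborn bile ducts. The comparison therefore asks which liver transcripts differ when an Mdr2 allele is missing. Total estimated counts per library were 14644529 and 11944157 in wild-type and 12991301, 16596923 and 17312851 in heterozygous livers, over 36401 Ensembl genes. The labels number the libraries within each genotype and keep the genotypes as littermates, without saying which pups shared a litter. They do not state outright that each library is a separate animal, so the p-values measure the spread between these samples only. Levels are given as normalised CPM (counts scaled to library size), mean ± SD over the wild-type (n = 2) and heterozygous (n = 3) libraries, wild-type first. The log2 fold change (log2FC) is heterozygous minus wild-type.

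Abcb4 itself (ENSMUSG00000042476, chromosome 5, 8893717 to 8959231, plus strand, mm10) fell from 162 ± 0.0278 CPM in wild-type to 97.0 ± 4.07 CPM in heterozygous livers. The heterozygous level was 0.598 of the wild-type level (log2 fold change -0.74, SE 0.06, adjusted p = 3.4e-04), and each of the 3 heterozygous libraries lay below both wild-type libraries. Genes around Abcb4 on chromosome 5 were also compared. Of 35 tested neighbours, 1 rose and 1 fell, with the same numbers adjusted over the list alone. The neighbour that fell was Cyp51, a sterol demethylase of cholesterol synthesis (87.8 ± 16.7 to 34.3 ± 7.18 CPM, log2FC -1.35), and the neighbour that rose was Steap4, a metalloreductase (108 ± 15.2 to 147 ± 3.93 CPM, log2FC 0.45). Steap4 lost its call without wild-type replicate 1 (adjusted p = 0.0624). Ankib1 (log2FC 0.23, adjusted p = 0.0673) and Dbf4 (log2FC -0.35, adjusted p = 0.0687) did not pass. The neighbours had a median of -0.01 and a mean of 0.03, and the set test pointed upwards without passing (camera adjusted p = 0.696).

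Across the transcriptome, 1680 of 13959 tested genes differed between the genotypes (12%), with 925 higher and 755 lower in heterozygous livers. Changes of at least 2-fold were seen in 131 of the higher and 91 of the lower genes. The first principal component held 49.7% of the variance and separated the genotypes. All 1680 called genes had groups that did not overlap, as did 45.5% of all tested genes, where random grouping gives 20% on average. Genes are not independent, so the share in a single grouping can lie far from that average. The count fell to 697 without wild-type replicate 1, 907 without wild-type replicate 2, 838 without heterozygous replicate 2 and 1068 without heterozygous replicate 3. Scaling by library size alone, with no TMM factors, turned the split to 704 higher and 936 lower.

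Fold changes followed transcript length. Across 13571 genes with an annotated length, the log2 fold change correlated with length (Spearman rho = 0.274; genes are not independent replicates). The shortest 20% of genes, up to 1848 bases, had a median log2 fold change of -0.13 with 102 genes higher and 305 lower. The longest 20%, above 5164 bases, had a median of 0.11 with 366 higher and 53 lower. Among ribosomal protein genes, which are short and were looked at after the values were seen, 50 of 79 fell and 0 rose (median -0.25, and -0.29 by library size alone). With an offset for transcript length 14 of them fell (median -0.13). Over all genes, 1251 genes differed with that offset, of which 1111 were among the 1680.

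Among the genes with the largest rises, A2m, the broad protease inhibitor alpha-2-macroglobulin, went from 18.5 ± 5.18 to 189 ± 35.6 CPM (log2FC 3.34, SE 0.19, adjusted p = 4.3e-05), a 10.1-fold difference. Car3, a cytosolic carbonic anhydrase, went from 80.3 ± 4.01 to 375 ± 46.3 CPM (log2FC 2.22, SE 0.11, adjusted p = 1.9e-05). Lrtm1, a leucine-rich repeat membrane protein, rose (2.74 ± 0.895 to 17.6 ± 1.05 CPM, log2FC 2.65). Rag1, the recombinase of developing lymphocytes (0.730 ± 0.556 to 3.51 ± 0.909 CPM, log2FC 2.15), Ms4a3, a marker of granulocyte progenitors (0.309 ± 0.157 to 1.92 ± 0.285 CPM, log2FC 2.65), and Fam129c (1.22 ± 0.420 to 5.62 ± 0.451 CPM, log2FC 2.16) rose from low levels. Cml3 (0.474 ± 0.0762 to 2.82 ± 0.693 CPM, log2FC 2.55) and Gm11128 (0.207 ± 0.174 to 1.58 ± 0.297 CPM, log2FC 2.80), both acetyltransferase genes of the Nat8 family, and Gm10319 (0.568 ± 0.149 to 3.19 ± 1.26 CPM, log2FC 2.48) rose too. Gm11505 had 3 rounded counts in wild-type and 39 in heterozygous livers, a heterozygous over wild-type ratio of 7.37 (exact 95% interval 2.34 to 37.3, counting error only; adjusted p = 0.0210). Akap2, an anchor for protein kinase A, had 0 counts in the wild-type group against a floor of 0.113 CPM over the group (3 counts) and 3.33 CPM in the heterozygous group, at least 29.5-fold higher than that floor. The exact 95% lower limit of the ratio, which also counts sampling error in the heterozygous group, was 23.7. Akap2, Fam129c and Rag1 each overlap another counted gene on the same strand, and Gm11505 lies antisense to Mpo, so part of their reads is uncertain. Single libraries decided some values. Calls were lost for Gm11505 without wild-type replicate 2 (adjusted p = 0.0869) or heterozygous replicate 2 (0.0551) and for Gm10319 without wild-type replicate 1 (0.0929). Without wild-type replicate 1 the log2FC was 3.33 for Rag1 and 4.10 for Gm11128.

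The largest falls were led by Hamp, which encodes hepcidin, the liver hormone that lowers iron export. Hamp went from 80.3 ± 12.4 to 4.08 ± 1.32 CPM (log2FC -4.27, SE 0.17, adjusted p = 7.3e-06), 19.3-fold lower. Apoa4, an apolipoprotein of triglyceride-rich particles, went from 520.4 ± 271 to 53.2 ± 5.02 CPM (log2FC -3.29, SE 0.25, adjusted p = 2.0e-04), and the gene BC023105 went from 83.8 ± 41.0 to 5.71 ± 1.18 CPM (log2FC -3.88, SE 0.29, adjusted p = 1.8e-04). Cox6b2, a testis-type subunit of cytochrome c oxidase (18.4 ± 2.10 to 2.70 ± 0.939 CPM, log2FC -2.81), Arl2bp, a binding partner of the small GTPase Arl2 (8.29 ± 3.50 to 1.72 ± 0.145 CPM, log2FC -2.25), Cgref1 (2.81 ± 0.426 to 0.391 ± 0.216 CPM, log2FC -2.82) and 1700123I01Rik (2.44 ± 0.474 to 0.536 ± 0.227 CPM, log2FC -2.18) also fell. Tgtp1, an interferon-inducible GTPase, fell from 98.7 ± 41.1 to 21.9 ± 3.10 CPM, and its near-identical copy Tgtp2 makes the assignment of its reads uncertain. Hsd3b5, a steroid dehydrogenase of male-type liver (4.60 ± 3.61 to 0.845 ± 0.335 CPM, log2FC -2.42), Noxa1, an activator of NADPH oxidase (0.925 ± 0.000496 to 0.190 ± 0.178 CPM, log2FC -2.36), and Hsf2bp (0.877 ± 0.306 to 0.177 ± 0.0571 CPM, log2FC -2.25) passed at low levels. Spdya had 20 rounded counts in wild-type and 1 in heterozygous livers, a wild-type over heterozygous ratio of 35.3 (exact 95% interval 5.64 to 1462; adjusted p = 0.00442). Its single heterozygous count was in replicate 3, and Spdya was tested in 10 of 15 alternative fits and called in 10. Noxa1, Hsf2bp, Hsd3b5 and Spdya each overlap another counted gene on the opposite strand, for Noxa1 the more abundant Entpd8 (mean 683 counts). Tgtp1 overlaps Gm12185 on the same strand. Part of the reads of these genes is therefore uncertain. Leaving out single libraries ended the call of Hsf2bp (wild-type replicate 2, adjusted p = 0.104). It also ended the calls of Hsd3b5 (wild-type replicate 2 or heterozygous replicate 2 or 3, 0.0518 to 0.111) and Noxa1 (either wild-type replicate or heterozygous replicate 2 or 3, 0.0638 to 0.114). Robust limma also ended the call of Hsd3b5 (0.0630). Without wild-type replicate 1 the log2FC was -3.27 for BC023105 and -3.11 for Hsd3b5. Without wild-type replicate 2 it was -2.63 for Apoa4 and -1.30 for Hsd3b5, and without heterozygous replicate 1 -3.26 for Noxa1.

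**Figure D1:**
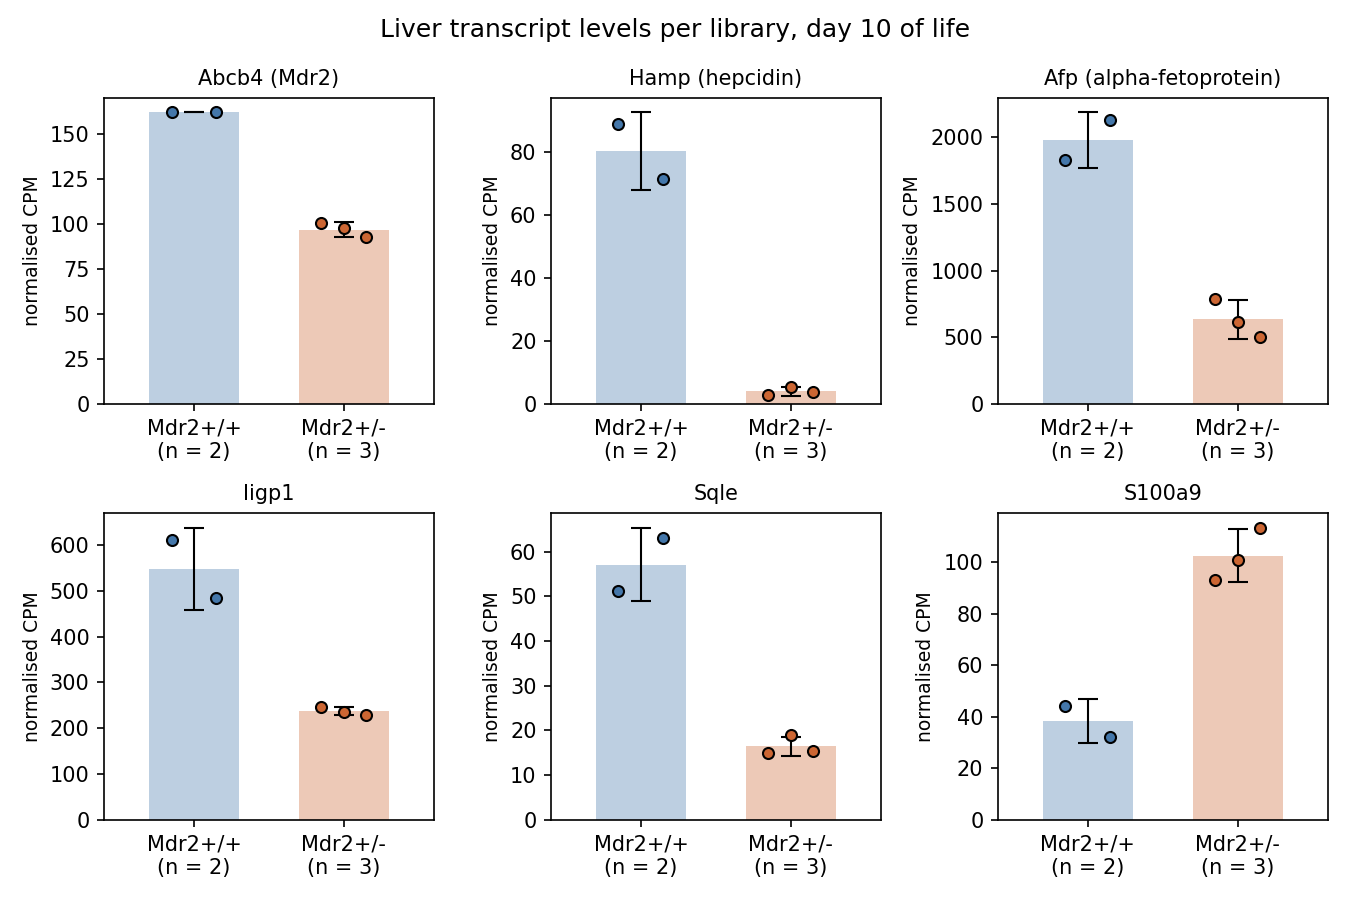
Normalised CPM of Abcb4, Hamp, Afp, Iigp1, Sqle and S100a9 in each liver library, with bars at the group mean and error bars of 1 SD for Mdr2+/+ (n = 2) and Mdr2+/- (n = 3). Abcb4 lies between 92.6 and 101 CPM in the heterozygous libraries and at 162 CPM in both wild-type libraries, and only S100a9 is higher in the heterozygous group among the 6 genes.

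Blood cell markers split by lineage. Neutrophil and myeloid progenitor genes were higher as a list: 18 of 22 tested members rose and 0 fell (21 higher and 0 lower adjusted over the list alone), with a median log2 fold change of 1.39 (camera adjusted p = 3.2e-15, and adjusted p = 0.408 with an estimated correlation and 0.0225 in fry). The granule genes Mpo (7.56 ± 1.64 to 26.7 ± 3.69 CPM, log2FC 1.81), Ltf (15.4 ± 4.82 to 55.0 ± 8.10 CPM, log2FC 1.82) and Ngp (28.2 ± 8.96 to 94.5 ± 12.2 CPM, log2FC 1.73) rose, as did S100a9, a calprotectin subunit (38.3 ± 8.45 to 103 ± 10.2 CPM, log2FC 1.41). B cell lineage genes rose in 12 of 17 cases (14 higher and 1 lower adjusted over the list alone). Across the list the median was 1.38 (camera adjusted p = 1.3e-08, and adjusted p = 0.408 with an estimated correlation and 0.0225 in fry). They included the receptor component Cd79b (4.35 ± 0.202 to 9.94 ± 0.937 CPM, log2FC 1.19), the precursor B cell gene Vpreb3 (0.952 ± 0.319 to 3.56 ± 0.409 CPM, log2FC 1.93), Fcrla (1.37 ± 0.0290 to 5.10 ± 0.877 CPM, log2FC 1.88) and the co-activator gene Pou2af1 (2.07 ± 1.37 to 8.51 ± 0.947 CPM, log2FC 1.98), whose log2FC was 2.95 without wild-type replicate 1. Erythroid genes went the other way, with 19 of 23 lower (1 higher and 22 lower adjusted over the list alone). The median log2FC was -0.76 (camera adjusted p = 8.2e-13, and adjusted p = 0.408 with an estimated correlation and 0.0225 in fry). The globin gene Hba-a1 (log2FC -0.88, adjusted p = 9.7e-04), near-identical to Hba-a2, the anion exchanger Slc4a1 (157 ± 20.8 to 95.4 ± 1.30 CPM, log2FC -0.72) and Hemgn (27.2 ± 0.758 to 15.7 ± 0.464 CPM, log2FC -0.79) fell. The 1 member that rose was Tfrc, the transferrin receptor, from 191 ± 8.50 to 345 ± 10.3 CPM; it takes up iron in many cell types. Megakaryocyte and platelet genes had a median of 0.30 with 1 of 15 higher (1 higher and 0 lower adjusted over the list alone; camera adjusted p = 0.0230, and adjusted p = 0.683 with an estimated correlation and 0.304 in fry), the integrin Itgb3 (12.7 ± 1.72 to 21.7 ± 3.11 CPM, log2FC 0.77). Ppbp, Gp6 and Gp5 did not pass (adjusted p = 0.0550, 0.0798 and 0.141), although Ppbp did without wild-type replicate 1 (0.0239). The platelet median was 0.65 without wild-type replicate 1, 0.15 without wild-type replicate 2 and 0.17 without heterozygous replicate 2. The platelet list was not called without wild-type replicate 2 (adjusted p = 0.632) or heterozygous replicate 2 (0.107), and Itgb3 not without wild-type replicate 2 (0.0586).

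T cell and natural killer cell markers included a single called gene: 1 of 17 fell and 0 rose, with 0 passing adjusted over the list alone (median -0.26, camera adjusted p = 0.178). Cd3e, a T cell receptor chain, fell (1.04 ± 0.0728 to 0.435 ± 0.0750 CPM, log2FC -1.25) but lost its call with any single library left out (adjusted p = 0.0696 to 0.160) and with the length offset (0.0534), and kept it in 4 of 14 alternative fits. Zap70 (log2FC 0.96, adjusted p = 0.0838), Foxp3 (log2FC -1.01, adjusted p = 0.0918) and Gzmb (log2FC -0.70, adjusted p = 0.103) did not pass, although Foxp3 did without heterozygous replicate 2 (0.0224). Without wild-type replicate 2 the list passed as lower (adjusted p = 0.00465).

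Interferon-stimulated genes were lower as a list: 14 of 34 tested members were lower and 0 higher (0 higher and 18 lower adjusted over the list alone), with a median of -0.41 (camera adjusted p = 8.3e-08, and adjusted p = 0.562 with an estimated correlation and 0.120 in fry). Without wild-type replicate 1 this median was -0.27. The interferon-inducible GTPase Iigp1 went from 548 ± 89.5 to 237 ± 8.75 CPM (log2FC -1.21, SE 0.09, adjusted p = 2.0e-04). Another such GTPase, Gbp2 (39.3 ± 4.97 to 17.7 ± 1.31 CPM, log2FC -1.16), and the immunoproteasome subunit Psmb9 (66.9 ± 16.0 to 25.2 ± 1.33 CPM, log2FC -1.41) fell. The class II antigen presentation list was written with co-stimulatory genes (such as Cd80 and Cd86) and dendritic cell markers (such as Itgax and Xcr1) beside class II genes. Of its tested members, 6 of 13 were lower and 1 higher (1 higher and 7 lower adjusted over the list alone). For the list as a whole the median was -0.71 (camera adjusted p = 0.00175, and adjusted p = 0.544 with an estimated correlation and 0.0903 in fry). The invariant chain Cd74 (81.8 ± 27.5 to 39.4 ± 1.00 CPM, log2FC -1.06), H2-Ab1 (27.0 ± 9.01 to 11.8 ± 1.20 CPM, log2FC -1.20), H2-Aa (21.3 ± 4.02 to 11.7 ± 1.08 CPM, log2FC -0.86) and H2-DMa (6.76 ± 0.994 to 3.58 ± 0.161 CPM, log2FC -0.92) fell, while the activation marker Cd83, named after its values were seen, was higher (log2FC 0.80, adjusted p = 0.0414). H2-DMa lost its call without wild-type replicate 1 (adjusted p = 0.0756), and Cd83 lost its call with any single library left out (0.0611 to 0.155) and in DESeq2 (0.130), keeping it in 8 of 15 alternative fits. The class II median was -0.43 with no filter and -0.43 with the 10-count filter. Cd74 had a log2FC of -0.67 without wild-type replicate 1, and robust limma ended its call (0.0528).

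Macrophage and Kupffer cell markers moved in both directions, with 4 of 24 higher and 5 lower (5 higher and 6 lower adjusted over the list alone). Of the 24, 7 are also abundant in neutrophils or monocytes and were set aside after the values were seen. The other 17 had a median log2FC of -0.32 and were not tested as a list. Lyz2, a lysozyme also made by neutrophils (29.7 ± 7.50 to 60.6 ± 0.837 CPM, log2FC 1.02), and the integrin Itgam, also on neutrophils (2.93 ± 0.338 to 7.12 ± 0.481 CPM, log2FC 1.27), rose. The scavenger receptor Msr1 (28.2 ± 0.805 to 19.2 ± 1.28 CPM, log2FC -0.56) and Aif1 (11.8 ± 2.33 to 7.26 ± 0.746 CPM, log2FC -0.72) fell. Named after their values were seen, Ly6c2 and Lyz1 were also higher (log2FC 1.11 and 0.72), and Cd163, Marco and C1qb lower (log2FC -0.58, -1.03 and -0.35). Calls were lost for Ly6c2 without wild-type replicate 1 or 2 or heterozygous replicate 3 (adjusted p = 0.0522 to 0.0972), Lyz1 without wild-type replicate 1 or 2 or heterozygous replicate 2 or 3 (0.0589 to 0.0825) and Cd163 without wild-type replicate 1 or heterozygous replicate 2 or 3 (0.0701 to 0.175, log2FC -0.37 without wild-type replicate 1). The same held for Marco without wild-type replicate 1 or heterozygous replicate 1, 2 or 3 (adjusted p = 0.0511 to 0.0956, log2FC -0.37 without wild-type replicate 1) and C1qb without wild-type replicate 1 or heterozygous replicate 2 or 3 (0.115 to 0.266, log2FC -0.20 without wild-type replicate 1). C1qb was also lost with the length offset (log2FC -0.21, 0.233). Of the alternative fits, Marco kept its call in 9 of 15, C1qb in 10 of 15, Lyz1 in 10 of 15 and Ly6c2 in 11 of 15. The list had a median of -0.08, a mean of 0.01 and a downward test that did not pass (camera adjusted p = 0.852), and it passed as lower without wild-type replicate 2 (0.0440). Aif1 was not called without wild-type replicate 1 (adjusted p = 0.132) or heterozygous replicate 3 (0.0532) or with the length offset (0.0557). 

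Of 20 tested chemokines and cytokines, 1 rose and 1 fell, in the same numbers adjusted over the list alone (median -0.12, camera adjusted p = 0.384). Cxcl14 rose (1.12 ± 0.280 to 3.32 ± 0.765 CPM, log2FC 1.54) and Cxcl9, an interferon-induced chemokine, fell (19.7 ± 8.88 to 10.8 ± 0.710 CPM, log2FC -0.88), while Il18 (log2FC -0.37, adjusted p = 0.0812) and Cxcl10 (log2FC -0.56, adjusted p = 0.218) did not pass. Over the alternative fits the log2FC of Cxcl9 ran from -1.26 to -0.31. Cxcl14 lost its call without wild-type replicate 2 (adjusted p = 0.0707), and Cxcl9 without wild-type replicate 1 or any heterozygous library (0.0676 to 0.215) and with robust limma (0.137). Without wild-type replicate 1 Cxcl10 turned to 0.14, and without wild-type replicate 2 it passed as lower (0.0180), as did the whole list (0.0112).

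Acute phase genes leaned higher, with 6 of 21 higher and 2 lower (8 higher and 2 lower adjusted over the list alone). The list median was 0.14 (camera adjusted p = 0.0187, and adjusted p = 0.545 with an estimated correlation and 0.0670 in fry). With the length offset that median was 0.22. Saa4 (75 ± 2.35 to 109.7 ± 3.13 CPM, log2FC 0.55) and the siderophore-binding protein Lcn2 (17.5 ± 0.687 to 28.9 ± 4.69 CPM, log2FC 0.73) rose along with Steap4, and Hamp and the pentraxin Apcs (log2FC -0.27, adjusted p = 0.0492), the latter named after its values were seen, fell. The list was not called without wild-type replicate 1 (adjusted p = 0.114). Lcn2 lost its call without either wild-type replicate (adjusted p = 0.0519 and 0.0524), and Apcs with any library but wild-type replicate 1 left out (0.0885 to 0.25), and with the length offset (0.375). Apcs kept its call in 7 of 15 alternative fits.

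Genes of mature hepatocytes were higher in 9 of 23 cases and lower in 2 (11 higher and 2 lower adjusted over the list alone). Across the list the median was 0.17 (camera adjusted p = 0.00713, and adjusted p = 0.562 with an estimated correlation and 0.0819 in fry). Tdo2, which starts tryptophan breakdown, went from 322 ± 34.0 to 669 ± 27.5 CPM (log2FC 1.05, SE 0.08, adjusted p = 2.0e-04). The urea cycle enzyme Cps1 (1276 ± 137 to 2329.8 ± 236 CPM, log2FC 0.87), complement C3 (9337 ± 68.1 to 13547 ± 747 CPM, log2FC 0.54) and histidine ammonia-lyase Hal (93.1 ± 0.579 to 137 ± 18.3 CPM, log2FC 0.55) rose. The members that fell, glutamine synthetase Glul and the apolipoprotein Apoa1, were named after their values were seen (log2FC -0.44 and -0.21). Calls were lost for Glul without wild-type replicate 1 or 2 (adjusted p = 0.0585 to 0.0768) and Apoa1 without wild-type replicate 1 or heterozygous replicate 1, 2 or 3 (0.0731 to 0.199). Apoa1 was also lost with the length offset (log2FC -0.07, 0.536) and kept its call in 8 of 15 alternative fits. Without wild-type replicate 1 neither the list (median 0.09, adjusted p = 0.133) nor Hal (0.0570) was called, and without wild-type replicate 2 the median was 0.26. 

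Fetal liver and imprinted genes split evenly, with 4 of 17 higher and 4 lower (5 higher and 4 lower adjusted over the list alone). Afp, the fetal serum protein alpha-fetoprotein, fell from 1976 ± 211 to 636 ± 145 CPM (log2 fold change -1.63, SE 0.15, adjusted p = 5.6e-04). The imprinted noncoding RNA Meg3 (10.1 ± 1.21 to 21.5 ± 1.44 CPM, log2FC 1.08) and the fetal growth factor Igf2 (4220.5 ± 5.64 to 5414 ± 397 CPM, log2FC 0.36) rose, and the surface marker Cd24a fell (82.5 ± 6.2 to 64.9 ± 2.95 CPM, log2FC -0.35). Named after their values were seen, Igf2bp3 and Igf2r were higher (log2FC 0.35 and 0.24) and Plagl1 and Gpc3 lower (log2FC -0.55 and -0.43). Calls were lost for Igf2bp3 without wild-type replicate 1 or 2 or heterozygous replicate 1 or 2 (adjusted p = 0.0531 to 0.112) and Igf2r with any library left out (0.0685 to 0.114), and for Plagl1 without wild-type replicate 2 or heterozygous replicate 2 or 3 (adjusted p = 0.0516 to 0.0918) and Gpc3 without wild-type replicate 1 or heterozygous replicate 2 or 3 (0.0683 to 0.145, log2FC -0.26 without wild-type replicate 1). Igf2r was also lost with the length offset (log2FC 0.10, 0.354) and kept its call in 6 of 15 alternative fits. The fetal list had a median of 0.01, a mean of -0.04 and an upward test that did not pass (camera adjusted p = 0.852). Igf2 was not called without wild-type replicate 1 (adjusted p = 0.0514) or heterozygous replicate 2 (0.0601), nor Cd24a without wild-type replicate 1 (0.0952). 

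Cell cycle genes were lower in 10 of 31 cases and higher in 0 (0 higher and 12 lower adjusted over the list alone). The median log2FC was -0.25 (camera adjusted p = 1.1e-06, and adjusted p = 0.408 with an estimated correlation and 0.0477 in fry). This median was -0.13 without wild-type replicate 1. Ccnd1 (158 ± 16.0 to 103 ± 7.89 CPM, log2FC -0.62), the replication clamp Pcna (84.7 ± 5.05 to 61.9 ± 3.11 CPM, log2FC -0.45), Rrm2 (54.2 ± 0.131 to 42.9 ± 0.803 CPM, log2FC -0.34) and Tyms (42.8 ± 1.93 to 33.7 ± 1.57 CPM, log2FC -0.34) fell, Tyms without a call when wild-type replicate 1 or heterozygous replicate 2 or 3 was left out (adjusted p = 0.0578 to 0.0972).

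Cholesterol synthesis genes were lower as a list: 15 of 24 tested members were lower and 0 higher (0 higher and 16 lower adjusted over the list alone), with a median of -0.53 (camera adjusted p = 1.9e-08, and adjusted p = 0.562 with an estimated correlation and 0.101 in fry). Leaving out wild-type replicate 2 gave a median of -0.28. Squalene epoxidase Sqle went from 57.2 ± 8.27 to 16.4 ± 2.17 CPM (log2FC -1.79, SE 0.12, adjusted p = 8.8e-05). Fdps (107 ± 16.0 to 36.1 ± 3.61 CPM, log2FC -1.57), Nsdhl (44.4 ± 10.4 to 16.3 ± 2.55 CPM, log2FC -1.44) and Lss (41.3 ± 6.62 to 19.6 ± 1.57 CPM, log2FC -1.07), enzymes of the same pathway, also fell. Fatty acid and triglyceride synthesis genes moved apart, with 1 of 17 higher and 3 lower (2 higher and 6 lower adjusted over the list alone). For the list as a whole the median was -0.13 (camera adjusted p = 0.178). Srebf1, the transcription factor of lipogenesis, rose (235 ± 0.494 to 388 ± 8.74 CPM, log2FC 0.72), whereas the elongase Elovl6 (9.94 ± 0.610 to 4.94 ± 1.09 CPM, log2FC -1.01), malic enzyme Me1 (49.3 ± 4.05 to 36.2 ± 2.52 CPM, log2FC -0.44) and Pnpla3 (4.40 ± 0.0359 to 2.70 ± 0.0755 CPM, log2FC -0.71) fell. Elovl6 lost its call without wild-type replicate 1 (adjusted p = 0.0624), Me1 without wild-type replicate 2 (0.0666), and Pnpla3 with any single library left out (0.0596 to 0.123), in DESeq2 (0.149) and with the length offset (0.0619). The list passed as lower without wild-type replicate 1 (median -0.28, adjusted p = 0.0319), and its median was 0.03 without wild-type replicate 2.

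Fatty acid oxidation genes were lower in 9 of 29 cases and higher in 1 (1 higher and 10 lower adjusted over the list alone). The list median was -0.17 (camera adjusted p = 0.00575, and adjusted p = 0.712 with an estimated correlation and 0.127 in fry). The omega-oxidation enzymes Cyp4a10 (189 ± 4.50 to 82.2 ± 4.47 CPM, log2FC -1.20), Cyp4a31 (41.7 ± 0.766 to 28.4 ± 1.17 CPM, log2FC -0.55) and Cyp4a14 (684 ± 26.0 to 491 ± 9.89 CPM, log2FC -0.48), which are close paralogs, and the pantetheinase Vnn1 (56.1 ± 6.78 to 34.1 ± 3.24 CPM, log2FC -0.72) fell. The member that rose was Ppara, the nuclear receptor that drives these genes, named after its values were seen (from 52.6 ± 2.41 to 95.8 ± 18 CPM, log2 fold change 0.86). The list lost its call without wild-type replicate 2 (median -0.04, adjusted p = 0.351), and Ppara without wild-type replicate 1 (0.0503).

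Hepatocyte transporters were higher in 6 of 17 cases and lower in 2 (9 higher and 3 lower adjusted over the list alone; median 0.23), and as a list did not pass (camera adjusted p = 0.0524, and adjusted p = 0.545 with an estimated correlation and 0.0346 in fry). The uptake carrier Slco2b1 went from 8.49 ± 0.608 to 18.8 ± 1.81 CPM (log2FC 1.16, SE 0.12, adjusted p = 8.5e-04). The sterol exporter pair Abcg5 (77.2 ± 0.742 to 111 ± 5.39 CPM, log2FC 0.52) and Abcg8 (95.8 ± 0.0124 to 140.4 ± 11.6 CPM, log2FC 0.55), which lie head to head, and the canalicular aminophospholipid flippase Atp8b1 (35.7 ± 1.22 to 51.8 ± 2.14 CPM, log2FC 0.54) rose. Ostb, a basolateral bile acid exporter subunit (log2FC -1.02, adjusted p = 0.0172), and Abcg2 (log2FC -0.30, adjusted p = 0.0367) fell; both were named after their values were seen. Ostb lost its call without either wild-type replicate (adjusted p = 0.105 and 0.0520), and Abcg2 when any library but heterozygous replicate 1 was left out (0.0561 to 0.178) and in DESeq2 (0.0583). The list passed without heterozygous replicate 3 (adjusted p = 0.0315), in robust limma (0.0149), with sample weights (0.0156), by library size (0.0398) and with the 10-count filter (0.0470).

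Bile acid synthesis and signalling genes showed no shared direction, with 3 of 17 higher and 1 lower (3 higher and 2 lower adjusted over the list alone). Across the list the median was 0.02 (camera adjusted p = 0.669). Cyp2c70, which makes muricholic acids, rose (308 ± 14.5 to 504 ± 48.1 CPM, log2FC 0.71), as did the co-receptor Klb (26.4 ± 2.10 to 34.2 ± 1.36 CPM, log2FC 0.38) and Akr1d1 (316 ± 38.2 to 396 ± 19.1 CPM, log2FC 0.33), while the sterol hydroxylase Cyp8b1 fell (248 ± 7.51 to 180.4 ± 23.0 CPM, log2FC -0.46). Calls were lost for Cyp8b1 without either wild-type replicate or heterozygous replicate 3 (adjusted p = 0.0521 to 0.0825), for Klb without wild-type replicate 1 or heterozygous replicate 2 (0.122 and 0.0676) and for Akr1d1 with any library but wild-type replicate 2 left out (0.0506 to 0.191). Among genes of phosphatidylcholine, the lipid that Abcb4 moves, 4 of 15 rose and 1 fell (5 higher and 2 lower adjusted over the list alone; camera adjusted p = 0.852). The phosphatidylcholine transfer protein Pctp went from 28.6 ± 1.41 to 16.1 ± 1.40 CPM (log2FC -0.83, SE 0.09, adjusted p = 0.00110), and Gnmt (159.6 ± 19.4 to 274 ± 40.4 CPM, log2FC 0.78), Etnk1 (45.9 ± 2.76 to 63.4 ± 0.321 CPM, log2FC 0.47) and Mat1a (2186 ± 191 to 2791 ± 47.0 CPM, log2FC 0.35) rose, Mat1a without a call when wild-type replicate 1 or heterozygous replicate 2 was left out (adjusted p = 0.0524 and 0.0540). Pcyt1a, named after its values were seen, was higher (log2FC 0.23), and lost its call with any library left out (adjusted p = 0.0633 to 0.215) and with the length offset (log2FC 0.17, 0.130). Of the alternative fits, 3 of 15 kept it. The median of this list was -0.06 while its mean was 0.03 and its test pointed upwards.

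Markers of bile ducts, stellate cells and endothelium did not pass as lists. Of 15 cholangiocyte and ductular markers, 2 rose and 1 fell, in the same numbers adjusted over the list alone (median 0.39, camera adjusted p = 0.454). This median was 0.06 without wild-type replicate 2 and 0.07 without heterozygous replicate 2. Prom1 (58.9 ± 0.193 to 78.4 ± 2.91 CPM, log2FC 0.41) and the keratin Krt23 (25 ± 0.292 to 34.1 ± 5.06 CPM, log2FC 0.44) rose, Cd24a fell, and the osteopontin gene Spp1 did not pass (log2FC -0.30, adjusted p = 0.102). Cd24a was not called without wild-type replicate 1 (adjusted p = 0.0952). Krt23 lost its call when any library but heterozygous replicate 3 was left out (adjusted p = 0.0744 to 0.150), by library size (0.0561) and with sample weights (0.0654), whereas Spp1 passed as lower without wild-type replicate 1 (0.0327) and with no filter (0.0267). Of 23 stellate cell and fibrosis markers, 1 rose and 1 fell, again the same numbers adjusted over the list alone (median 0.10, camera adjusted p = 0.384). Their median was -0.00745 without wild-type replicate 1, 0.16 without heterozygous replicate 1 and 0.06 without heterozygous replicate 2. Reln rose (192 ± 6.57 to 268 ± 15.7 CPM, log2FC 0.48) and Vim fell (68.2 ± 5.64 to 53.1 ± 3.65 CPM, log2FC -0.36), and Lrat (log2FC 0.20, adjusted p = 0.0814) and the collagen Col3a1 (log2FC 0.33, adjusted p = 0.0564) did not pass. Vim lost its call without wild-type replicate 2 or heterozygous replicate 2 (adjusted p = 0.117 and 0.0678), and Col3a1 passed as higher without wild-type replicate 2 or heterozygous replicate 1 (0.0272 and 0.0431), in DESeq2 (0.0177) and in limma (0.0392 robust, 0.0394 weighted). Sinusoidal endothelial markers had 3 of 17 lower and 0 higher (0 higher and 4 lower adjusted over the list alone). Their median was 0.00, their mean -0.03 and their test pointed down without passing (camera adjusted p = 0.593). Clec4g (59.6 ± 5.12 to 45.0 ± 1.63 CPM, log2FC -0.40), Fcgr2b (33.6 ± 3.31 to 25.9 ± 1.01 CPM, log2FC -0.37) and Oit3 (47.8 ± 4.69 to 39.4 ± 0.705 CPM, log2FC -0.28) fell and Gpr182 did not pass (log2FC -0.21, adjusted p = 0.0645). None of the calls on Clec4g, Fcgr2b and Oit3 held without wild-type replicate 2 (adjusted p = 0.0556, 0.128 and 0.227); those on Fcgr2b and Oit3 were also lost without heterozygous replicate 1 (0.0542 and 0.0870) or 2 (0.0776 and 0.125), and that on Oit3 without heterozygous replicate 3 (0.0974). Oit3 kept its call in 6 of 15 alternative fits, losing it also in DESeq2 (0.112) and with the length offset (0.0709).

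Xenobiotic metabolism genes were higher in 8 of 38 cases and lower in 2 (11 higher and 3 lower adjusted over the list alone). The median log2FC was 0.15 (camera adjusted p = 0.0479, and adjusted p = 0.562 with an estimated correlation and 0.152 in fry). Aldh1b1 (118 ± 9.01 to 196 ± 7.50 CPM, log2FC 0.73) and Ugt2b1 (176 ± 24.1 to 245 ± 2.84 CPM, log2FC 0.48) rose, and the glutathione transferase Gstt1 fell (156 ± 3.60 to 125 ± 1.93 CPM, log2FC -0.33). Cyp2c37, named after its values were seen, also fell (log2FC -0.34). The call was lost for Cyp2c37 without wild-type replicate 1 or heterozygous replicate 1, 2 or 3 (adjusted p = 0.0614 to 0.162, log2FC -0.19 without wild-type replicate 1) and with the length offset (log2FC -0.27, 0.0763), and kept in 9 of 15 alternative fits. The list was not called without wild-type replicate 1 (adjusted p = 0.255) or heterozygous replicate 2 (median 0.09, adjusted p = 0.113) or with a GC offset (0.0503), nor was Gstt1 with the length offset (0.0679). Endoplasmic reticulum stress genes were lower in 7 of 23 cases and higher in 2 (2 higher and 9 lower adjusted over the list alone). For the list as a whole the median was -0.19 (camera adjusted p = 0.0284, and adjusted p = 0.562 with an estimated correlation and 0.102 in fry). Manf (75 ± 2.61 to 46.9 ± 4.21 CPM, log2FC -0.67) and asparagine synthetase Asns (13.5 ± 1.31 to 8.22 ± 0.726 CPM, log2FC -0.72) fell, and the sensor Atf6 (38.8 ± 2.68 to 48.8 ± 1.36 CPM, log2FC 0.33) and Edem1 (124 ± 15.1 to 163 ± 10.6 CPM, log2FC 0.40) rose. The list was not called without wild-type replicate 2 (adjusted p = 0.111) or heterozygous replicate 1 (0.0890). Atf6 and Edem1 were not called without wild-type replicate 1 (adjusted p = 0.116 and 0.123) or heterozygous replicate 2 (both 0.0638) or with the length offset (0.104 and 0.0662). Oxidative stress genes had 2 of 20 lower and 0 higher (0 higher and 3 lower adjusted over the list alone). The list median was -0.07 (camera adjusted p = 0.178), and the list passed as lower without wild-type replicate 1 (0.0277). Gstm1 (log2FC -0.43, adjusted p = 0.0137) and Ephx1 (log2FC -0.28, adjusted p = 0.0266) fell and neither was called without wild-type replicate 2 (0.0861 and 0.141); Ephx1 was also lost without heterozygous replicate 2 (0.0788) or 3 (0.0869) and with the length offset (0.0816). Akr1b8 (log2FC -0.53, adjusted p = 0.0546) and Gclm (log2FC 0.20, adjusted p = 0.0820) did not pass.

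Fasting-response genes had 3 of 17 higher and 3 lower (6 higher and 3 lower adjusted over the list alone). Across the list the median was 0.06 (camera adjusted p = 0.669). The growth factor binding proteins Igfbp2 (2343 ± 412 to 1335 ± 139.6 CPM, log2FC -0.81) and Igfbp1 (703 ± 31.3 to 482 ± 49.3 CPM, log2FC -0.54) fell. Serine dehydratase Sds (39.8 ± 5.25 to 88.1 ± 28.1 CPM, log2FC 1.16) rose, without a call when either wild-type replicate was left out (adjusted p = 0.108 and 0.0508) or in robust limma (0.180). Creb3l3 was also higher and Pklr lower, both named after their values were seen (log2FC 0.28 and -0.25). Calls were lost for Creb3l3 without wild-type replicate 1 or 2 or heterozygous replicate 1 or 2 (adjusted p = 0.0519 to 0.115) and Pklr without wild-type replicate 1 or heterozygous replicate 1, 2 or 3 (0.0533 to 0.153). Circadian clock genes had a median of 0.21 with 3 of 18 higher and 0 lower (6 higher and 0 lower adjusted over the list alone; camera adjusted p = 0.0230, and adjusted p = 0.408 with an estimated correlation and 0.0225 in fry). Clock and Nr1d2 rose (log2 fold changes 0.29 and 0.36; adjusted p = 0.0413 and 0.0494) and Per2 did not pass (log2FC 0.34, adjusted p = 0.0667). The clock list was not called without wild-type replicate 1 (adjusted p = 0.0663), with the length offset (0.0690), with no filter (0.0544) or with the 10-count filter (0.0656). Clock kept its call in 5 of 15 and Nr1d2 in 5 of 15 alternative fits, both losing it with the length offset (0.276 and 0.0940), by library size (0.0802 and 0.0637) and in DESeq2 (0.166 and 0.0866). Nr1d2 kept its call only without heterozygous replicate 3 (adjusted p with any other library left out = 0.0519 to 0.281), and Clock lost it in each such fit (0.0775 to 0.163). Per2 passed without heterozygous replicate 2 (0.0499). Immediate early and heat shock genes, which respond to handling, had 2 of 27 lower and 0 higher (0 higher and 2 lower adjusted over the list alone). The median log2FC was -0.01 (camera adjusted p = 0.852). Gadd45b (7.41 ± 0.110 to 3.20 ± 0.645 CPM, log2FC -1.21) and Hsp90aa1 (log2FC -0.29, adjusted p = 0.0191) fell, and Hspa8 (log2FC -0.24, adjusted p = 0.0622) and Btg2 (log2FC 0.32, adjusted p = 0.0959) did not pass. Hsp90aa1 lost its call when any library but heterozygous replicate 3 was left out (0.0517 to 0.0814).

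Sex-linked genes separated a single library from the others. Heterozygous replicate 1 had 78.1 Ddx3y CPM and 11.1 Xist CPM, the pattern of a male, while the other 4 libraries had 284 to 424 Xist CPM and at most 2.25 Ddx3y CPM. Without that library 1174 genes differed. Of 12 tested sex-linked and sex-biased genes, 0 rose and 1 fell, the same numbers adjusted over the list alone (median 0.11, mean 1.09, camera adjusted p = 0.852). The gene that fell was Hsd3b5, and Ddx3y (adjusted p = 0.136), Eif2s3y (0.146) and Cyp2b9 (log2FC 0.20, adjusted p = 0.0821) did not pass. Of the exocrine pancreas markers, 4 were tested and 0 passed: Amy2a5, Pnliprp1, Amy2b and Cela1 (adjusted p = 0.143, 0.736, 0.753 and 0.970). Amy2a5 passed as lower without wild-type replicate 1 (0.0270). Of the striated muscle and adipose markers only Acta1 was tested, and it did not pass (log2FC -0.07, adjusted p = 0.830). The list of mitochondrially encoded genes had 0 members among the gene identifiers and was not analysed here.

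**Figure D2:**
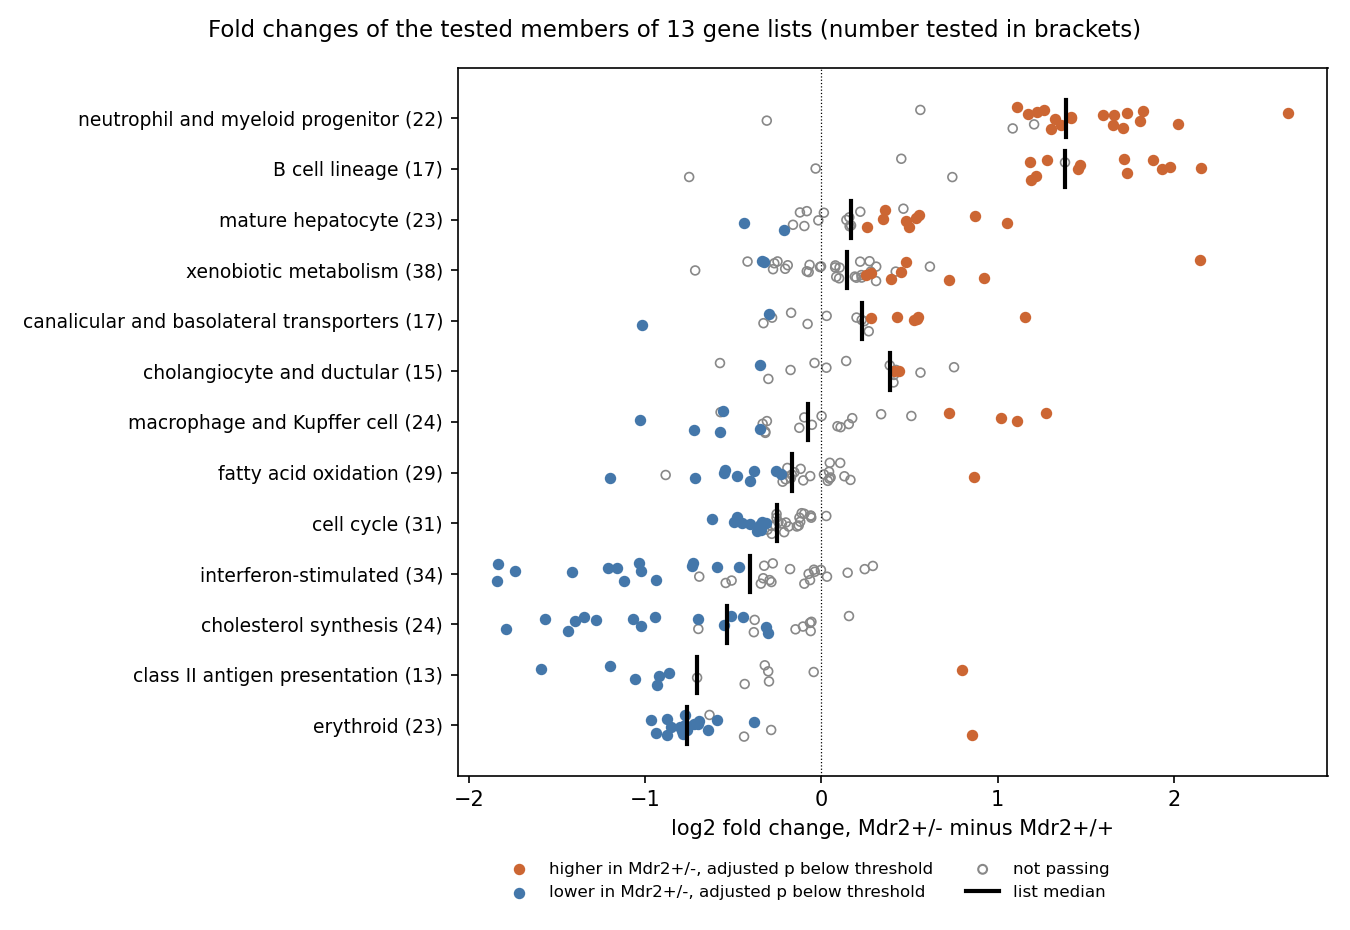
Log2 fold change, Mdr2+/- minus Mdr2+/+, of each tested member of 13 gene lists, with filled points for members past the adjusted p threshold of 0.05, open points for the rest and a vertical bar at each list median. Medians run from -0.76 for the 23 erythroid genes to 1.39 for the 22 neutrophil and myeloid progenitor genes.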

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

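The offsets for GC content and transcript length were chosen after seeing the data. Abcb4 kept its direction and call in all 15 alternatives that test single genes, with log2 fold changes of -0.78 to -0.71 and adjusted p of 4.7e-16 to 0.00261. Counts of differing genes ranged from 1212 in the DESeq2 Wald test to 2177 with no filter (1512 at 10 counts or more, 1662 with DESeq2 size factors, 1640 by library size, 1849 in robust and 1512 in weighted limma, 1703 and 1251 with GC and length offsets). Leaving out a library gave 697 to 1174 genes (345 to 670 higher, 352 to 504 lower) and 12 to 15 lists; fewer samples enter those fits, and a lone wild-type library is assumed to vary like the heterozygous ones. The list calls fell from 14 to 0 with an estimated correlation and to 6 in fry, and were 12 to 15 otherwise. The estimated correlations replace the preset 0.01, and fry compares a list with no other genes. With the replicate number as a replicate block, 1277 genes (730 higher, 547 lower) and 13 lists passed. Heterozygous replicate 3 stands alone in its block, so in that fit the genotype comparison rests on replicates 1 and 2 of each genotype, with little left to estimate spread. Same-numbered libraries deviated together by 0.03 and 0.03 in correlation over 2 pairs. The deviations of the 2 wild-type libraries mirror each other (correlation -1), so these values cannot show whether same-numbered libraries are paired. The labels do not say that they are. Of the single-gene comparisons under all alternatives, 2444 kept direction and call, 247 lost and 35 gained a call and 12 turned; of the list comparisons these numbers were 413, 38, 11 and 18.

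Genes without a call that passed in some alternatives included Ppbp (4 of 15), Hspa8 (4 of 15), Akr1b8 (3 of 15), Ddx3y (2 of 12), Eif2s3y (2 of 13), Zap70 (1 of 15), Btg2 (1 of 15), Gpr182 (1 of 15) and Cyp2b9 (1 of 15). Every result that turned was uncalled in both fits, and the cause was not tested. The fetal list turned down with no filter (median -0.0803), with sample weights (-0.0249) and with the length offset (-0.0322), and the genes flanking Abcb4 at 10 counts or more (-0.0311) and with the length offset (-0.00781). The macrophage list tested upwards by library size (median -0.116), with the length offset (-0.0263) and in fry (-0.0760). Acta1 turned under the block (0.0219) and Acta1 and Cela1 with the length offset (0.0217 and 0.115). Over the fits that leave out a library, medians ran over -0.0825 to 0.0130 (phosphatidylcholine), -0.29 to -0.0593 (chemokines), -0.25 to 0.0725 (macrophage), -0.54 to -0.0311 (T and natural killer cells), -0.100 to 0.18 (immediate early), -0.0704 to 0.12 (fetal), -0.0465 to 0.0254 (flanking) and -0.0163 to 0.22 (sex-linked). Other uncalled lists had medians of -0.0562 to 0.11 (bile acid), -0.0124 to 0.19 (fasting response), -0.0944 to 0.0188 (endothelial) and -0.18 to -0.0537 (oxidative stress). Single genes ran over -0.99 to 0.14 (Cxcl10), -0.25 to 0.16 (Acta1), -0.0892 to 0.31 (Pnliprp1), -0.40 to 0.15 (Amy2b), -0.0752 to 0.0373 (Cela1) and -0.0789 to 0.0497 (Smad7). Pseudocounts and limma without a trend were planned for normalised values and were not run on counts, and the Wald test has no list test. Depth sets a floor of 0.173 to 0.251 CPM per library (3 counts).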

Other observations

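All tests of explanations in this part were chosen after the results were seen, and the genes of the next paragraphs were picked after their values were seen. Hamp2, the second hepcidin gene, whose reads can be shared with Hamp, fell (24.3 ± 0.323 to 7.04 ± 2.76 CPM, log2FC -1.76), and so did Id1 (21.7 ± 7.71 to 8.95 ± 1.95 CPM, log2FC -1.31) and Atoh8 (13.3 ± 1.23 to 5.47 ± 0.637 CPM, log2FC -1.27), which respond to bone morphogenetic proteins in hepatocytes. Smad6 (log2FC -0.18, adjusted p = 0.392) and Smad7 (log2FC -0.02, adjusted p = 0.935), targets of the same pathway, did not pass. The iron exporter Slc40a1 (298 ± 16.2 to 397 ± 12.7 CPM, log2FC 0.41) and the iron importer Slc11a2 (34.9 ± 0.962 to 45.2 ± 1.87 CPM, log2FC 0.37) rose along with Tfrc, Slc11a2 without a call when wild-type replicate 2 was left out (adjusted p = 0.0555). The protease inhibitors of the A2m family rose as well: Mug1 (133 ± 19.2 to 437 ± 83.8 CPM, log2FC 1.72) and Mug2 (13 ± 1.5 to 43.5 ± 7.10 CPM, log2FC 1.73), near-identical genes that share reads, and Pzp (5409.8 ± 193 to 6916 ± 583 CPM, log2FC 0.35). A2m, Mug1, Mug2 and Pzp all lie on chromosome 6, and whether their rises share a local cause was not tested. Pzp was not called without wild-type replicate 1 or heterozygous replicate 1 or 2 (adjusted p = 0.0601 to 0.0854) or with sample weights (0.0637).

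All 11 of 11 tested guanylate-binding protein genes fell, with a median log2 fold change of -0.94 (-0.94 with DESeq2 size factors and -0.98 by library size). These genes are close copies whose reads can be split among them; Gbp3 (35.4 ± 13.6 to 10.6 ± 1.93 CPM, log2FC -1.74) and Gbp7 (66.4 ± 16.3 to 32.4 ± 1.09 CPM, log2FC -1.04) were among them. The other immunoproteasome subunits Psmb8 (97.6 ± 25.8 to 45.1 ± 0.872 CPM, log2FC -1.12) and Psmb10 (79.9 ± 8.90 to 37.9 ± 1.70 CPM, log2FC -1.08) and the activator genes Psme1 (132 ± 16.3 to 83.4 ± 2.33 CPM, log2FC -0.67) and Psme2 (90.3 ± 7.65 to 54.5 ± 2.09 CPM, log2FC -0.73) fell too.

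Short transcripts were lower and long transcripts higher in heterozygous livers. No single library carried this. Slopes were fitted to each gene's deviation from its mean log2 CPM over all libraries, for 10426 better expressed genes. Per doubling of length they were -0.0429 and -0.0555 in the wild-type libraries and 0.0546, 0.0224 and 0.0215 in the heterozygous ones. The gap was 0.0644, against ranges of 0.0126 and 0.0331 within the groups. Slopes of deviations balance around 0 over the libraries, so some opposite signs are built in. GC content showed no such trend (Spearman rho = -0.00780 across genes). Ribosomal protein genes had a median of -0.25, against -0.13 for 10000 sets of other genes matched on longest transcript length and expression, of which 0% lay as low. Matched on principal transcript length instead, which was run second, the sets had a median of -0.18 and 0.09% lay as low. The sets were made of genes drawn singly, so they do not allow for ribosomal protein genes moving together. Their median also moved with the length measure used. These shares therefore cannot decide whether short length alone explains the fall. Differences in RNA quality, library preparation or litter that go with genotype may produce the trend and cannot be told apart from genotype, because 0 label fields differ between the libraries once genotype, titles, descriptions and file names are set aside. Numbers in those file names fall in separate ranges for the genotypes, and the labels do not say what they stand for.

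Lower interferon-stimulated and class II genes could reflect fewer macrophages, local strain variants or the length trend. Fewer macrophages and Kupffer cells would lower their markers by as much. Among all 24 markers, 2 lay at or below the class II median, but 7 of the 24 are also abundant in neutrophils or monocytes. The other 17 had a median log2FC of -0.32. Of these, 5 (29.4%, exact 95% interval 10.3 to 56.0%), Marco, Aif1, Cd163 and Msr1 among them, lay at or below the interferon median of -0.41. At or below the class II median lay 2 (11.8%, 1.46 to 36.4%), and 5 at its value with no filter (-0.43), with an interval that again passes 50%. These intervals treat the markers as independent, but the correlation estimated over all 24 was 0.53, so the intervals are only a rough guide. Fewer such cells therefore cannot be told apart from lower expression within cells, because these markers are few, correlated and spread widely. Dendritic cells, whose markers the class II list itself holds, were not tested in this way. Variants carried on chromosome 5 with the Mdr2 allele, or on chromosome 17 at the histocompatibility complex, could change genes near them. Of the 20 called genes, 11 lie elsewhere, Cd74 among them, where such a local effect would not reach. For the 7 on chromosome 17, the 1 on chromosome 5 and the 1 without coordinates this stays open. Gene positions cannot speak to a carried variant that acts on genes of other chromosomes, or to segments carried elsewhere, so these stay open for all 20. With the length offset the interferon median was -0.38 and the class II median -0.79 (camera adjusted p = 3.1e-08 and 0.00108 at the preset correlation). Without the offset, camera called neither list with an estimated correlation (adjusted p = 0.562 and 0.544). Genotype and litter stay open and were not tested apart.

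Erythroid genes fell (19 of 23 tested) while neutrophil (18 of 22) and B lineage genes (12 of 17) rose. With an estimated correlation camera called none of the 3 lists (adjusted p = 0.408 for each). A different share of hepatocytes would move the 3 lists alike, but the neutrophil and erythroid medians differed by 2.15, with quartiles of -0.80 to -0.64 for erythroid and 1.21 to 1.70 for neutrophil genes. With the length offset the erythroid median was -0.67 and those of the neutrophil and B lineage lists 1.59 and 1.36. Genotype, litter and the stage of liver maturation stay open and were not tested apart.

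Dividing the 5 libraries into groups of 2 and 3 can be done in 10 ways, too few for a share under 0.05. The division by genotype called 1680 genes and the highest of the others 2, so 1 division reached the count by genotype, itself. Every other division holds both genotypes in at least 1 of its groups. Any difference that goes with genotype, litter or preparation included, would therefore leave few calls there, and the contrast cannot tell these apart. Reads of 4 Y-linked genes (Ddx3y, Eif2s3y, Kdm5d and Uty) summed to 1753 counts in heterozygous replicate 1, 67 in replicate 3 and 2, 3 and 2 in wild-type replicates 1 and 2 and heterozygous replicate 2. Scaled to library size, replicate 3 held 2.87% of the level of replicate 1, and Xist in replicate 1 was 3.05% of the mean of the other 4 libraries.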
